A study of Sus scrofa with 12 samples.

How the data were processed

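Gene expression was measured in jejunal mucosa, the inner lining of the middle part of the small intestine, of 12 pigs aged 140 days. Per the labels, 6 pigs had high feed efficiency and 6 had low feed efficiency, that is, more or less growth for the feed eaten. Each group held 3 males and 3 females. How feed efficiency was scored, and the breed and diet of the pigs, are not given in the sources used here. Per the labels' protocols, total RNA was extracted with Qiazol, treated with DNase and purified on columns, copied to DNA with the Ambion WT Expression Kit, labelled with biotin and hybridized to 1-colour Affymetrix arrays of the pig Snowball design, with 1 array per pig and no pooling stated. A probe set is a group of short probes designed against 1 transcript or part of it.

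The authors deposited 1 log2 value per probe set and array. The submitters' processing notes name GCOS version 1.1.1, the Affymetrix operating software. The background correction, the summarization of probes to probe sets and the normalization between arrays are not given in the sources used here. The 12 columns had medians within 0.14 log2 units of each other, so no new normalization was applied in the main setting. On a log2 scale a difference of 1 is a doubling of signal. Background signal compresses the differences of dim probe sets, and the floor of the scale is shown by 12 negative control probe sets, whose highest mean was 1.90. Arrays have no read depth, and the number of arrays limits the precision: the median standard error of a difference between 6 and 6 pigs was 0.169 log2 units.

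The table held 47845 probe sets. The 123 control probe sets were left out. Of the other 47722, 26426 had 1 gene symbol in the platform annotation, 0 had several and 21296 were unnamed here. Symbols were updated through gene identifiers or unique synonyms of the RefSeq gene table of assembly Sscrofa11.1, which changed 446 symbols; the table was used for names only, and no coordinates are given because the array's probes were not placed on a genome. A symbol reached through a synonym can belong to a related gene. The set also held 1800 probe sets for microRNAs of species other than pig, which were tested like the others and are not named by gene. Probe sets with a mean over all arrays above the 25th percentile, 2.29 log2 units, were tested, which left 35791, of which 21967 had a symbol and covered 12579 genes.

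The comparisons and their tests, the 44 gene lists and the rule for naming genes were fixed before the data were examined, except where stated. Differences were fitted with limma 3.58.1 in R 4.3.3 (linear models with empirical Bayes variances), with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of 0.05. High against low feed efficiency was fitted over all 12 pigs with sex as an additive term, and male against female in the same model. The interaction of feed efficiency and sex, and the feed efficiency difference within each sex, came from a model of the 4 means of sex and group, which left 8 residual degrees of freedom. Printed adjusted p-values for probe sets are limma's. Values after a ± are SD over 6 pigs for group means, and standard errors (SE) are the model's.

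Of 44 gene lists covering cell types of the gut wall, digestion, transport, energy metabolism, protein turnover, immunity, stress and sex chromosomes, 42 had at least 4 measured genes and were tested with limma's camera at its preset inter-gene correlation of 0.01, with 1 probe set per gene, that of the highest mean. Camera asks whether the genes of a list shifted relative to all other genes. Each list was also tested with the correlation estimated from the data, with limma's fry, which asks whether a list's genes move on balance in one direction without reference to other genes, and by an exact two-sided permutation test of its mean over genes per pig, relabelling pigs within sex for feed efficiency and within feed efficiency group for sex (400 relabellings, smallest possible p 0.005). The permutation test, a fit with the spread of each array as a covariate and the markers of another tissue examined in 1 pig were added after the data were seen.

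Named genes were, for feed efficiency, 12 per direction: genes passing the threshold first, and otherwise those of the smallest unadjusted p, given as values that did not pass. Up to 4 members per list were taken by the smallest unadjusted p for feed efficiency. For sex, the measured genes of the sex-linked lists and 10 others were named; for the interaction 6 and within each sex 4. A set of genes of interest for digestion, mucus, hormones and metabolism was fixed as well, of which 13 are reported. Genes outside this rule are named where a count was small or a pattern was singled out, and are said to be so.

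The fits were tested on simulated data. For high against low feed efficiency over 35791 probe sets, 20.9% of probe sets changed by 0.6 log2 units were recovered, 64.2% of those changed by 1 and 92.4% of those changed by 2, while 3 of 35591 unchanged ones were called. These changes were planted together, in 67, 67 and 66 probe sets. The shares hold for that mix and the simulated spread, and recovery could be lower where fewer probe sets change. Alternatives covered the filter on dim probe sets, quantile normalization, centring of each array on its median, array weights, the variance model, the mean of a gene's probe sets, the covariates, the threshold, the set test and leaving out each pig. Pig identifiers fell into a lower and a higher run of numbers. The higher run held 2 high and 2 low feed efficiency pigs, all female. The labels do not call the runs batches, and the run was tried as a block. Where groups were compared over many probe sets, the comparison was repeated on 100 of 200 possible splits of the pigs. Values of dim probe sets, near the negative controls, are uncertain.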

Results

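Expression profiles of jejunal mucosa were available for 12 pigs, 6 with high and 6 with low feed efficiency, with 3 males and 3 females in each group. The series title states that pigs divergent in feed efficiency were contrasted in the jejunum, the part of the intestine where most sugars, peptides and fats are taken up. Array medians ran from 4.02 to 4.16 log2 units, and pairs of arrays correlated at 0.922 to 0.969 across probe sets. The spread of all probe sets within an array (SD of log2 values) was 2.20 ± 0.0469 (SD, n = 6) in the high group and 2.25 ± 0.0196 in the low group. The high feed efficiency male numbered replicate 1 stood apart: it had the lowest array weight, 0.402, against 0.698 to 1.64 for the other pigs, and its enterocyte markers (genes of the absorptive cells) averaged 8.28 log2 units against 9.43 over the other 5 pigs of its group.

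The first comparison asked which transcripts differed between pigs of high and low feed efficiency. No probe set passed the adjusted threshold among 35791 tested with limma, and the smallest adjusted p was 0.502. At an unadjusted p under 0.05 there were 2789 probe sets, 1365 higher and 1424 lower in the high group, where 1790 would be counted with no effect. The 12 genes of the smallest unadjusted p on the lower side are given first. DIO1, which activates thyroid hormone, had a mean of 4.01 ± 0.399 (SD, n = 6) log2 units in high and 4.88 ± 0.494 in low feed efficiency pigs, a difference of -0.87 (SE 0.167, limma adjusted p 0.526). LIPH, a membrane-bound phospholipase, differed by -1.03 (SE 0.208, limma adjusted p 0.579), a 2.04-fold lower signal in the high group, and all 6 high pigs lay below all 6 low pigs. CIDEB, a lipid droplet protein used in assembling lipid-rich lipoproteins, differed by -0.79 (SE 0.164), and SLC39A5, a zinc transporter, by -0.62 (SE 0.122). For CIDEB and SLC39A5 the 3 high feed efficiency males lay below all other pigs. The other genes on the lower side were SLC25A42, a mitochondrial coenzyme A carrier (-0.60), CCRL2, a chemokine receptor-like protein (-0.50), AQP11, an aquaporin (-0.84), NPAS2, a clock transcription factor (-0.49), SERPINB1, a protease inhibitor (-0.41), the kinesins KIFC3 (-1.43) and KIF21B (-0.58), and CLIP2, a microtubule-binding protein (-0.45). None of these differences passed the adjusted threshold.

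On the higher side, GUCY1A3, a subunit of the nitric oxide receptor that makes cyclic GMP, had a mean of 6.27 ± 0.288 in high and 5.50 ± 0.259 in low feed efficiency pigs, a difference of 0.77 (SE 0.156, limma adjusted p 0.581) or 1.71-fold. PDE3A, a phosphodiesterase that cyclic GMP inhibits, differed by 0.51 (SE 0.114), with all 6 high pigs above all 6 low pigs. SLC15A2, a peptide transporter, differed by 0.81 (SE 0.205), DDR2, a collagen receptor of stromal cells, by 0.54 (SE 0.134), and the transcription factors ETV1 and MEF2A by 0.59 (SE 0.132) and 0.42 (SE 0.106). The remaining 6 were PODXL (0.52), PAQR5 (0.63), UBE2H (0.52), S100PBP (0.55), NFXL1 (0.71) and NEGR1 (0.75), and again none passed. For MEF2A 3 of its 5 other probe sets had the same direction, and for NPAS2 and CLIP2 none of the others did. Over all tested probe sets, 101 had no overlap between the 6 high and 6 low pigs, against 77.5 if every ordering were equally likely (0.216%).

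**Figure D1:**
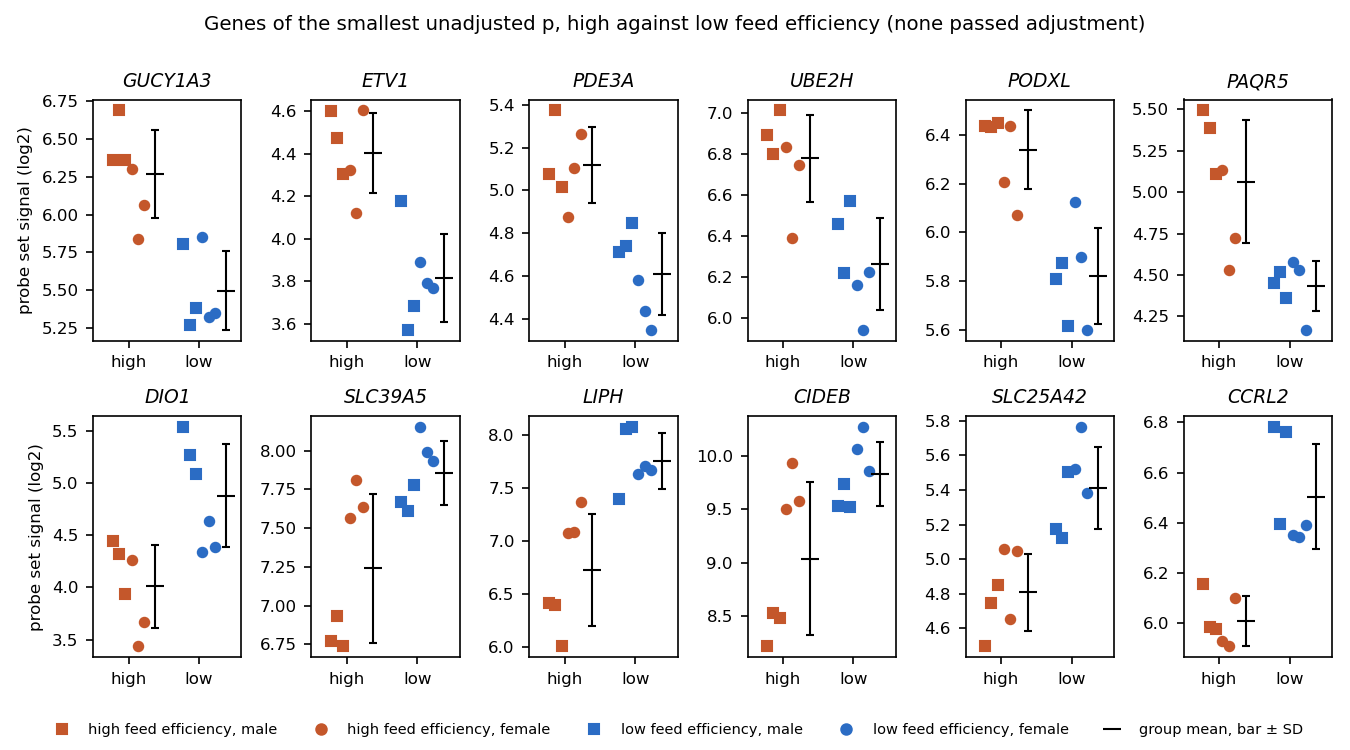
Log2 signal (vertical axes) in 6 high and 6 low feed efficiency pigs for the 6 genes of the smallest unadjusted p in each direction; each point is 1 pig, squares are males and circles females, and bars are group means ± SD. All 6 high pigs lie above the low group for PDE3A and below it for LIPH, SLC25A42 and CCRL2, but no gene passed the adjusted threshold.

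The genes fixed in advance for digestion and absorption differed between the groups by less than the larger of the SDs between pigs. Sucrase-isomaltase (SI) averaged 9.53 ± 1.43 in high and 9.86 ± 0.896 in low feed efficiency pigs (SD, n = 6), and lactase (LCT) 11.16 ± 1.17 and 11.63 ± 0.709. The glucose transporter SLC5A1 differed by -0.18 (SE 0.251), the peptide transporter SLC15A1 by -0.36 (SE 0.494) and the fatty acid binding protein FABP2 by -0.12 (SE 0.378). The mucin MUC2 differed by 0.34 (SE 0.273), the stem cell markers LGR5 and OLFM4 by 0.41 (SE 0.225) and -0.34 (SE 0.299), and the hormone genes CCK and GCG by -0.35 (SE 0.370) and 0.23 (SE 0.263). PIGR, which carries antibodies across the epithelium, averaged 12.90 in both groups. CPT1A, which admits fatty acids to mitochondria, differed by -0.43 (SE 0.295) and IGF1 by 0.11 (SE 0.209). None of the 13 had an unadjusted p under 0.05. High feed efficiency replicate 1 was the lowest of all pigs for SI, LCT, SLC5A1, SLC15A1 and FABP2, and the highest for MUC2. Without it the high pigs averaged 10.08 for SI, 9.74 for SLC15A1 and 9.84 for FABP2, each above the low mean. For SLC5A1 the group means were then about equal, and for LCT the high mean stayed lower. The signs for SI, SLC15A1 and FABP2 therefore rest on that pig.

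Gene lists were then compared. Of 42 lists, 11 were shifted between high and low feed efficiency by camera with its preset correlation, 10 of them lower and 1 higher in the high group. None of the 11 held with an estimated correlation, where the smallest adjusted p over lists was 0.774, and none held with fry (smallest adjusted p 0.147) or with exact permutation of list means (smallest adjusted p 0.105). At an unadjusted p under 0.05 these 3 tests gave 1, 7 and 5 lists. Epithelial junctions and glycolysis reached the smallest possible permutation p, 0.005, which adjusted to 0.105 over the 42 lists. Permutation could pass a list only if more lists had reached so small a p, so its lack of calls decides little. Without high feed efficiency replicate 1, whose enterocyte markers were low, 3 lists were called, without low feed efficiency replicate 1 there were 5, and without low feed efficiency replicate 6 there were 19. With array weights 4 lists were called, and with quantile normalization, which equalizes the spread of the arrays, 3 (proteasome, lipid absorption and fibroblast genes). No member of any list passed over all genes tested, and adjusted over the list alone 4 members of the called lists passed, given below, with 0 in the other 8 called lists.

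The arrays of the high group had the narrower spread, 2.20 against 2.25, and the set of called lists changed when it was adjusted for. The spread is computed from the same arrays as the lists, so adjusting for it can also remove a true shift. With that spread as a covariate, added after the data were seen, 9 lists were called. Of the 11, lipid absorption (-0.30), epithelial junctions (-0.13) and fibroblast genes (0.30) passed in the same direction, and ribosomal proteins passed in the opposite direction, at 0.11 (adjusted p 0.00683). The others did not pass. Proteasome subunits went from -0.27 to -0.04 (adjusted p 0.395), oxidative phosphorylation from -0.18 to -0.01 (adjusted p 0.764), MHC class I presentation from -0.20 to -0.07 (adjusted p 0.277) and T cell markers from -0.20 to -0.10 (adjusted p 0.208). Glycolysis, xenobiotic and antioxidant genes were at -0.13, -0.14 and 0.033 (adjusted p 0.269, 0.274 and 0.995). With quantile normalization the 3 lists still called, proteasome, lipid absorption and fibroblast genes, were at -0.19, -0.20 and 0.20. Oxidative phosphorylation, MHC class I, junction and antioxidant genes were at -0.10, -0.11, -0.08 and -0.12 (adjusted p 0.177, 0.299, 0.218 and 0.218), and ribosomal, glycolysis, xenobiotic and T cell genes at -0.13, -0.14, -0.17 and -0.15 (adjusted p 0.218, 0.308, 0.170 and 0.170).

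The smallest adjusted p by camera was that of subunits of the proteasome, the complex that degrades tagged proteins. Of 27 measured subunits 26 were lower in the high group, 6 at an unadjusted p under 0.05, and the list averaged 7.84 ± 0.247 in high and 8.11 ± 0.167 in low feed efficiency pigs (camera adjusted p 1.07e-05; adjusted p = 0.774 with an estimated correlation). Of the 6 high pigs, 5 lay below the low median. PSMA5 differed by -0.59 (SE 0.165), PSMA4 by -0.67 (SE 0.259) and PSMA6 by -0.29 (SE 0.112). Nuclear-encoded genes of oxidative phosphorylation, the mitochondrial machinery that makes ATP, were lower for 33 of 37 members, with a mean difference of -0.18 and 5 of 6 high pigs below the low median (camera adjusted p 0.00105; adjusted p = 0.774 with an estimated correlation). Its members of the smallest p were the complex I subunits NDUFB6 (-0.56), NDUFB8 (-0.49) and NDUFB1 (-0.46). Cytosolic ribosomal proteins were lower for 47 of 55 members, with a mean difference of -0.18 and 4 of 6 high pigs below the low median (camera adjusted p 0.0113; adjusted p = 0.858 with an estimated correlation). RPL27 differed by -0.90 (SE 0.288) and RPS25 by -0.86 (SE 0.359), while RPS3A, at 2.89 and 2.60 log2 units near the floor of the scale, differed by 0.29. Without high feed efficiency replicate 4, replicate 3 or low feed efficiency replicate 2 the ribosomal list had adjusted p of 0.225, 0.090 and 0.0863, with mean differences of -0.10, -0.14 and -0.13.

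For lipid absorption and chylomicron assembly, the packaging of dietary fat, 24 of 27 members were lower, the list averaged 7.69 ± 0.453 in high and 7.95 ± 0.200 in low feed efficiency pigs (camera adjusted p 0.00794; adjusted p = 0.846 with an estimated correlation), and 1 member passed when adjusted over the list alone. CIDEB led it, followed by the sterol transporter ABCG8 (-0.51), the lipase PNPLA2 (-0.37) and AGPAT2 (-0.47). Without high feed efficiency replicate 1 its mean difference went from -0.27 to -0.09 (adjusted p 0.539), and without low feed efficiency replicate 1 to -0.20 (adjusted p 0.127). For epithelial junctions 16 of 21 members were lower, 2 passed when adjusted over the list alone, and all 6 high pigs lay below the low median, at means of 8.04 ± 0.124 and 8.21 ± 0.0636 (camera adjusted p 0.00576; adjusted p = 0.774 with an estimated correlation). They included the intestinal cadherin CDH17 (-0.61, SE 0.156), the desmosome gene PKP2 (-0.44, SE 0.127), F11R (-0.36) and the claudin CLDN4 (-0.53). Without high feed efficiency replicate 1 its adjusted p was 0.0519, with a mean difference of -0.17 both with and without that pig. Glycolysis and gluconeogenesis genes were lower for 17 of 20 members, with a mean difference of -0.20 and 5 of 6 high pigs below the low median (camera adjusted p 0.0187; adjusted p = 0.774 with an estimated correlation), among them FBP2 (-0.33) and TPI1 (-0.35). Without high feed efficiency replicate 1 its adjusted p was 0.120, and without low feed efficiency replicate 1 it was 0.104, with a mean difference of -0.19 in both.

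Detoxifying and antioxidant genes and 2 immune lists were lower as well. Xenobiotic and steroid metabolism was lower for 19 of 21 members, with a mean difference of -0.22 (camera adjusted p 0.0452; adjusted p = 0.857 with an estimated correlation), with the export pumps ABCG2 at -0.72 (SE 0.229) and ABCC2 at -0.82 (SE 0.287). Its mean difference was -0.07 without high feed efficiency replicate 1 (adjusted p 0.560), and -0.12 and -0.19 without low feed efficiency replicates 3 and 1 (adjusted p 0.283 and 0.191). It was -0.23 to -0.21 (adjusted p 0.0515 to 0.0624) without high feed efficiency replicate 3 or 4 or low feed efficiency replicate 4 or 5. Antioxidant genes were lower for 20 of 24 members, with a mean difference of -0.20 (camera adjusted p 0.0134; adjusted p = 0.774 with an estimated correlation), with PRDX1 at -0.31 and TXN at -0.37. MHC class I presentation was lower for 12 of 16 members, with a mean difference of -0.20, and 1 passed when adjusted over the list alone (camera adjusted p 0.0134; adjusted p = 0.774 with an estimated correlation). TAPBP, which helps load peptides onto MHC class I, differed by -0.63 (SE 0.173) and the transcription factor IRF1 by -0.32 (SE 0.123). T cell and cytotoxic lymphocyte markers were lower for 15 of 18 members, with a mean difference of -0.20 (camera adjusted p 0.0278; adjusted p = 0.846 with an estimated correlation), among them CD3E (-0.47, SE 0.150), the protease GZMB (-0.62, SE 0.242), CD3D (-0.52) and TBX21 (-0.23). Without high feed efficiency replicate 1 the adjusted p of the antioxidant, MHC class I and T cell lists was 0.0675, 0.198 and 0.452, with mean differences of -0.21, -0.17 and -0.14. Without low feed efficiency replicate 1 the last 2 had adjusted p of 0.127 and 0.104, with a mean difference of -0.19 in both. The T cell list had 0.168, 0.0693, 0.0640 and 0.0512 without low feed efficiency replicate 3 or 2 or high feed efficiency replicate 2 or 5, with mean differences of -0.15, -0.16, -0.17 and -0.22.

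The one list shifted upward was fibroblast and matrix genes, where 13 of 16 members were higher and the mean was 8.39 ± 0.345 in high and 8.28 ± 0.168 in low feed efficiency pigs (camera adjusted p 0.0462; adjusted p = 0.857 with an estimated correlation). FBN1, a microfibril protein, differed by 0.81 (SE 0.231), and no other member reached an unadjusted p under 0.05. High feed efficiency replicate 1 had the highest mean of this list, 8.81, and without it the mean difference went from 0.11 to 0.02 (adjusted p 0.539). The mean difference was 0.06 to 0.12 (adjusted p 0.0514 to 0.281) without high feed efficiency replicate 2, 5 or 6 or low feed efficiency replicate 1, 2 or 3. Smooth muscle and endothelial markers had mean differences of 0.10 and 0.05, with adjusted p of 0.117 and 0.122, so stromal lists other than the fibroblast list did not pass.

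In 4 of the 11 lists the difference had opposite signs in males and females. It was -0.49 in males and 0.09 in females for T cell markers, -0.61 and 0.08 for lipid absorption, -0.52 and 0.08 for xenobiotic genes, and 0.41 and -0.18 for fibroblast genes. None of these interactions passed by exact permutation (unadjusted p 0.03, 0.08, 0.17 and 0.085, adjusted p 0.420, 0.420, 0.476 and 0.420). That test could pass a list only if several of the 42 had reached its smallest possible p of 0.005. Its lack of calls therefore decides little. Leaving out 1 pig, the values in males ran from -0.54 to -0.42, -0.79 to -0.30, -0.69 to -0.25 and 0.29 to 0.59, the nearest to 0 each time without high feed efficiency replicate 1. Those in females turned to -0.03 for T cell markers without high feed efficiency replicate 6, to -0.05 and -0.10 for lipid absorption and xenobiotic genes without low feed efficiency replicate 6, and to 0.0055 for fibroblast genes without high feed efficiency replicate 4.

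**Figure D2:**
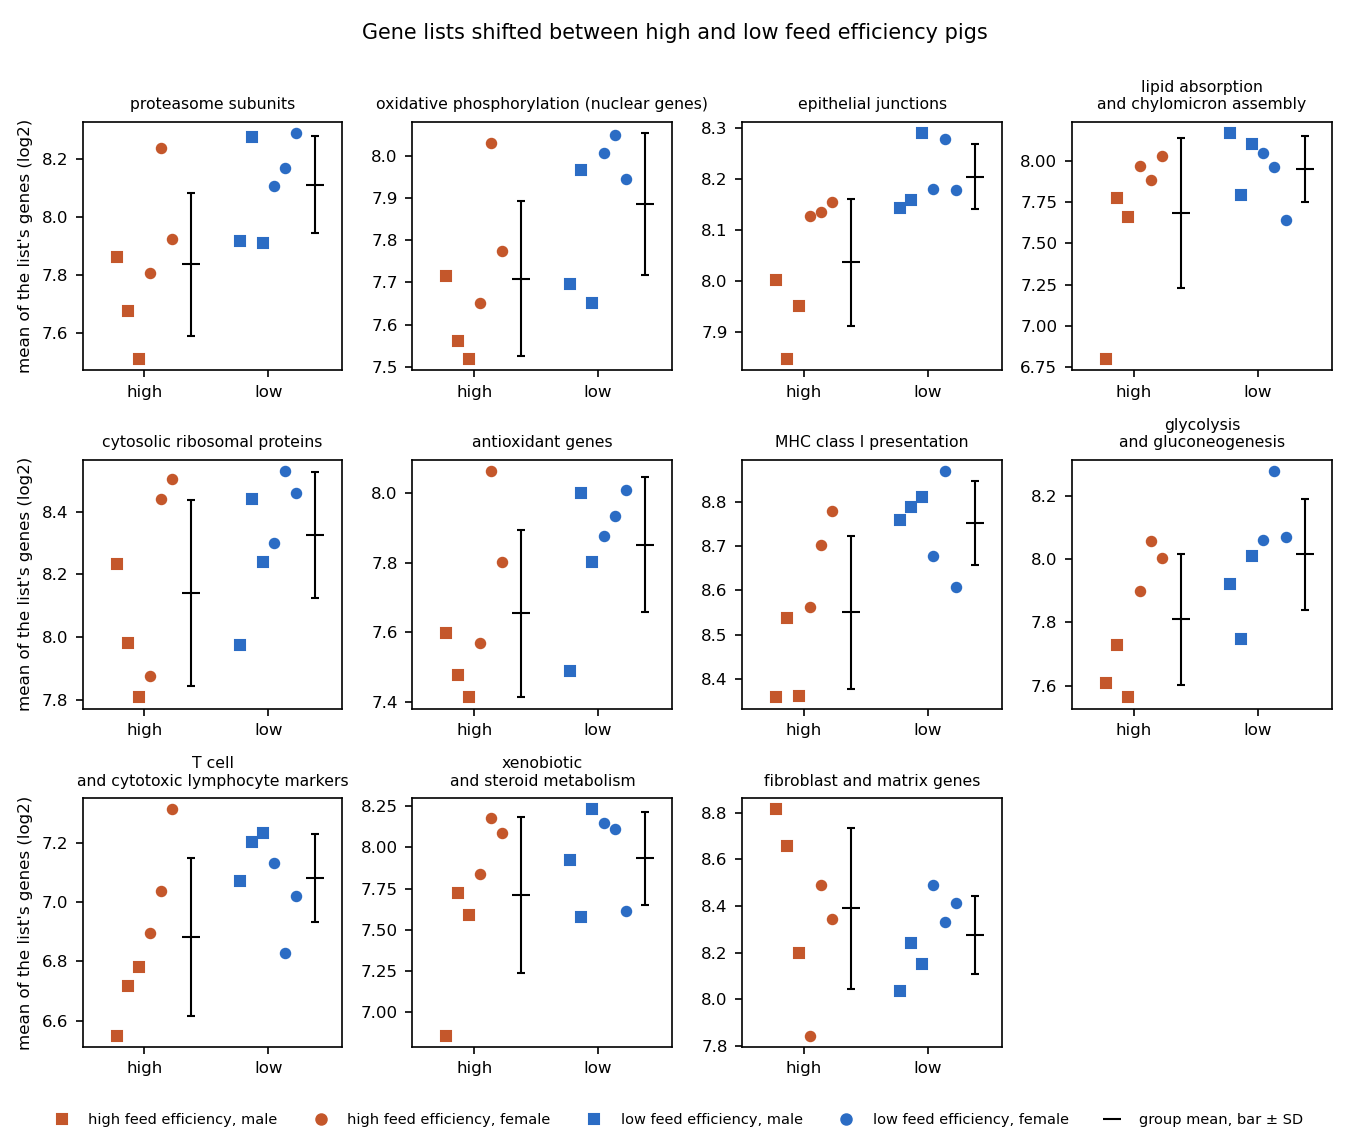
Mean log2 signal of the genes of each of the 11 shifted lists (vertical axes) in 6 high and 6 low feed efficiency pigs; each point is 1 pig, squares are males and circles females, and bars are group means ± SD. The groups overlap in all 11 lists, and for epithelial junctions the 3 high males lie lowest.

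The other 31 lists did not pass for feed efficiency. Carbohydrate digestion and transport had a mean difference of -0.27 (camera adjusted p 0.174), with the trehalase gene TREH at -0.67 (SE 0.319). Protein digestion and amino acid transport differed by -0.13 (adjusted p 0.260), fatty acid oxidation by -0.11 (adjusted p 0.0888), the citric acid cycle by -0.14 (adjusted p 0.117) and cholesterol synthesis by -0.14 (adjusted p 0.190). Within them SLC3A1, a subunit of an amino acid transporter, differed by -0.55 (SE 0.180), HADHA and HADHB, the trifunctional enzyme of fat oxidation, by -0.48 and -0.38, and citrate synthase (CS) by -0.41. Genes typical of the proximal small intestine differed by -0.17 on average (adjusted p 0.174), led by the calcium channel TRPV6 at -0.62 (SE 0.155) and the iron exporter SLC40A1 at -0.77 (SE 0.248). Clock genes had a mean difference of 0.11 (adjusted p 0.190), with PER3 at 0.58 and NPAS2 at -0.49. Goblet cell, enteroendocrine and enterocyte markers differed by -0.04, 0.08 and -0.17, with adjusted p of 0.878, 0.260 and 0.316. Without high feed efficiency replicate 1 the high pigs averaged 9.43, 8.71 and 7.37 for enterocyte markers, carbohydrate digestion and protein digestion. The low means were 9.41, 8.74 and 7.36. For goblet cell markers that pig was at 8.88, above the 7.26 to 8.24 of the other high pigs. Interferon-stimulated genes differed by -0.17 (adjusted p 0.279) and inflammatory mediators by -0.08 (adjusted p 0.834). In 7 of the 42 lists, none of them called, the median, the mean and the direction of the test did not share a sign. Adjusted over the list alone, 2 proximal small intestine genes, 1 mineral handling gene and 1 clock gene passed. TRPV6 and SLC40A1 belong to both the proximal and the mineral handling list, so the first 2 of these counts overlap.

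The second comparison was between male and female pigs. All males were in the lower run of pig identifiers, where high and low feed efficiency replicates 4 were the only females. Sex and run overlapped largely, so most differences below cannot be fully told apart from one between the runs. The 6 probe sets given next also passed with the run as a block. Of 35791 probe sets 6 passed, 2 higher and 4 lower in males, and in each of them no male overlapped a female. A probe set of KDM6A, an X-linked histone demethylase with a copy on the Y chromosome, was at 5.87 ± 0.144 in males and 2.30 ± 0.448 (SD, n = 6) in females (limma adjusted p 1.08e-06). Its 3 other probe sets had differences of 1.06, -0.98 and -0.60, none of which passed, and the one of the highest mean was lower in males. The other 5 probe sets are unnamed here. SNOWBALL_037083_st was at 1.92 ± 0.381 in males, about the level of the negative controls, and 7.99 ± 0.418 in females (limma adjusted p 9.34e-08). SNOWBALL_023078_st, SNOWBALL_033300_st and SNOWBALL_028804_st were lower in males by -5.44, -3.32 and -3.53, and SNOWBALL_035896_st was higher by 2.04. At an unadjusted p under 0.05 there were 3314 probe sets. Among probe sets differing between male and female pigs, averaging the probe sets of each gene, which leaves out unnamed ones, left 0 calls with limma, with 1156 genes at an unadjusted p under 0.05.

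**Figure D3:**
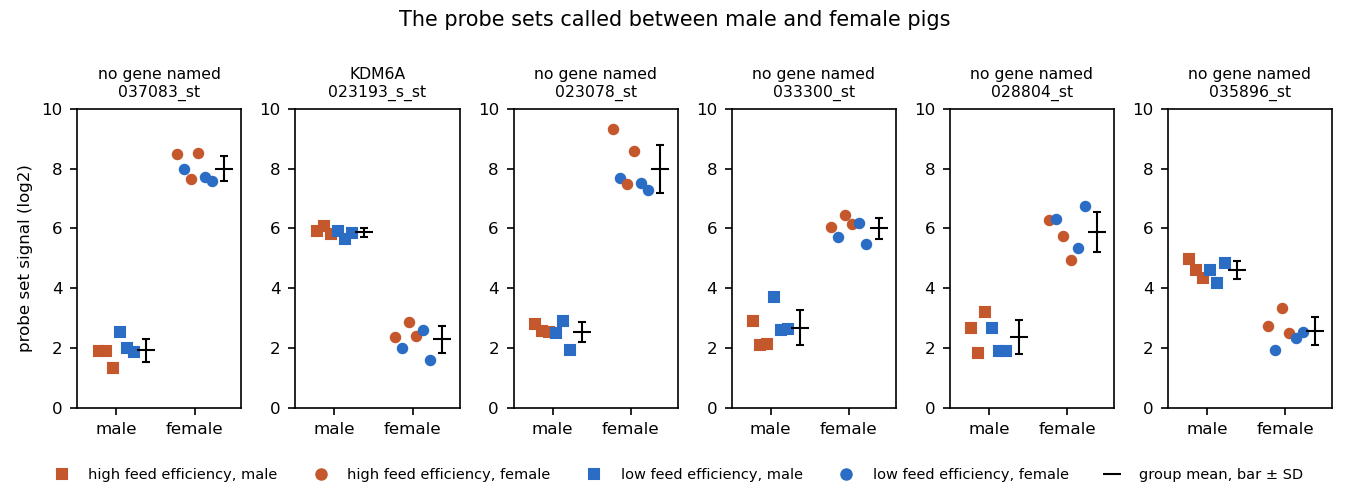
Log2 signal (vertical axes) of the 6 probe sets called between 6 male and 6 female pigs; each point is 1 pig, squares are males and circles females, colour gives the feed efficiency group and bars are means ± SD over the sex. Males and females do not overlap in any of the 6.

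Among the other named genes, none of which passed, ABHD4, a lipase, was at 6.89 ± 0.545 in males and 8.01 ± 0.139 in females (SD, n = 6), a difference of -1.13 (SE 0.179, limma adjusted p 0.158). It passed without high feed efficiency replicate 1 (-1.26, adjusted p 0.0178) and with array weights (-1.16, adjusted p 0.0346), and its adjusted p reached 0.849 with the run of pig identifiers as a block. HPGD, which inactivates prostaglandins, differed by -0.91 (SE 0.151), TRPV6 by -0.72 (SE 0.155), and CIDEB and SLC39A5, also named for feed efficiency, by -0.86 and -0.60. TMEM92 and KCTD2 differed by -0.90 and -0.52. BEND4, PPEF2 and KRT25 were higher in males by 0.88, 0.87 and 0.77. The probe set annotated to the Y-linked gene EIF1AY had signal in both sexes, 7.04 in males and 7.65 in females (-0.61, SE 0.194). Being the only measured member, it left the Y-linked list untested.

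For sex, 10 lists were shifted by camera and all were lower in males, none of them with an estimated correlation, where the smallest adjusted p was 0.168 and 3 lists had an unadjusted p under 0.05. Of these lists, 7 were also called lower in high feed efficiency pigs, where independent comparisons would share 2.4. Both comparisons count the high feed efficiency males in the lower group. No list member passed over all genes tested. In 7 of the 42 lists, none of them called, the median, the mean and the test did not share a sign. All 8 measured X-linked genes with Y copies were lower in males, with a mean of 7.21 ± 0.199 in males and 7.55 ± 0.152 in females (camera adjusted p 0.000455; adjusted p = 0.375 with an estimated correlation). EIF2S3, a translation initiation factor, differed by -0.73 (SE 0.138), KDM6A at its brightest probe set by -0.60 (SE 0.139), ZFX by -0.41 (SE 0.189) and TXLNG by -0.43, with USP9X at -0.26, UBA1 at -0.18, DDX3X at -0.08 and KDM5C at -0.07. Adjusted over the list alone, 2 of the 8 passed. With the probe set of the largest variance per gene, the mean of this list was 0.30 higher in males. That choice takes the KDM6A probe set at 3.57 in place of the one at -0.60, which alone is enough to turn the mean of 8 genes. The turn is therefore no sign that the list as a whole is higher in males.

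Of the other 9 lists, oxidative phosphorylation was lower for 33 of 37 members, 12 of them at an unadjusted p under 0.05, with all 6 males below the female median (camera adjusted p 4.65e-06; adjusted p = 0.460 with an estimated correlation). Fatty acid oxidation averaged 7.56 ± 0.164 in males and 7.75 ± 0.159 in females, and 6 of its 25 members passed when adjusted over the list alone (camera adjusted p 0.000637; adjusted p = 0.460 with an estimated correlation). Its members HADHA and CPT1A differed by -0.57 and -0.79, and the carnitine carrier SLC25A20, which lies outside the naming rule, by -0.72. CPT1A was at 6.14 and 6.26 in the females of the lower run, within the male range of 5.67 to 6.70. In the females of the higher run it was at 6.72 to 7.90. Glycolysis and gluconeogenesis differed by -0.30 and the citric acid cycle by -0.26 (camera adjusted p 0.000245 and 0.000969, and adjusted p = 0.168 and 0.287 with an estimated correlation). Both held PCK1, an enzyme of gluconeogenesis, at -1.18, a gene also outside the naming rule. Ribosomal proteins differed by -0.24 and proteasome subunits by -0.23 (camera adjusted p 6.87e-06 and 0.000387; adjusted p = 0.717 and 0.621 with an estimated correlation). Antioxidant, xenobiotic and lipid absorption genes differed by -0.24, -0.35 and -0.21 (camera adjusted p 0.00415, 0.0134 and 0.0209; adjusted p = 0.461, 0.717 and 0.750 with an estimated correlation), with 1, 0 and 2 members passing when adjusted over the list alone, and without high feed efficiency replicate 1 the last 2 had mean differences of -0.19 and -0.03 (adjusted p 0.231 and 0.849), and fatty acid oxidation went from -0.20 to -0.15 (adjusted p 0.0656). The xenobiotic list was also lost without low feed efficiency replicate 2 or high feed efficiency replicate 6 (-0.30 in both, adjusted p 0.114 and 0.0669). The lipid list was lost without high feed efficiency replicate 4, replicate 6 or low feed efficiency replicate 2 (-0.17, -0.15 and -0.19, adjusted p 0.175, 0.139 and 0.0839). With fry 3 lists passed, and with exact permutation none (smallest adjusted p 0.070). Glycolysis, citric acid cycle and X-linked genes reached the smallest possible permutation p, 0.005, so that test could pass a list only if more lists had done so. With the run of pig identifiers as a block 12 lists were called, 6 of the 10 among them, and 3 were higher in males: smooth muscle, fibroblast and endothelial genes. The ribosomal list then differed by 0.026. In that fit the sex difference rests on the males and the few females of the lower run. The arrays of males had a narrower spread, 2.20 ± 0.0405 (SD, n = 6) against 2.24 ± 0.0357 in females. With quantile normalization 9 lists were called, 7 of the 10 among them, and 2 were higher in males: smooth muscle and fibroblast genes. With the spread as a covariate, added after the data were seen, 9 lists were called, 6 of the 10 among them, and the fibroblast list was higher in males. The ribosomal, proteasome, antioxidant and xenobiotic lists were lost in that fit, at 0.021, -0.03, -0.05 and -0.28 (adjusted p 0.924, 0.421, 0.402 and 0.0504).

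The last comparison asked whether the feed efficiency difference depended on sex. No probe set passed for the interaction (smallest adjusted p 0.151 with limma), and 2395 had an unadjusted p under 0.05. For the iron exporter SLC40A1 the difference between high and low was -1.47 (SE 0.216) within males and -0.07 (SE 0.216) within females, an interaction of -1.40 (SE 0.305, limma adjusted p 0.743). FRK, a tyrosine kinase, differed by -1.14 within males and 0.12 within females. SLC4A5, TNFAIP8, PTGDR and IL20RB differed in opposite directions, with TNFAIP8 at 1.35 within males and -1.07 within females. None of these interactions passed.

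Within males no probe set passed (smallest adjusted p 0.121 with limma, 3121 at an unadjusted p under 0.05). LIPH differed by -1.57 (SE 0.205), CDH17 by -1.03 (SE 0.144) and KIFC3 by -2.26 (SE 0.321), with adjusted p of 0.121 each. KIFC3 was at 2.28 in 1 high feed efficiency male and below the highest negative control mean of 1.90 in the other 2, so the size of its difference is uncertain. With the mean of each gene's probe sets 6 genes passed within males, all lower in the high group: CDH17, LIPH, CIDEB, KIFC3, SLC39A5 and SMPDL3B, a lipid phosphodiesterase named after its value was seen. These within-sex values compare 3 with 3 pigs and use the spread estimated from all 4 groups. Within females no probe set passed (smallest adjusted p 0.200 with limma, 1947 at an unadjusted p under 0.05). GHRH, the gene of growth hormone releasing hormone, differed by -3.47 (SE 0.712, limma adjusted p 0.824) and passed in 2 alternatives, the fit on the 6 females alone and the fit without low feed efficiency replicate 3. Its level in high feed efficiency females, 0.61 to 1.22 log2 units, lay below the highest negative control mean of 1.90. PDCD1LG2, ZNF770 and IL20RB differed by 0.79, 0.87 and 1.56 within females, and none passed.

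High feed efficiency replicate 1, a male, had high signal for genes of the stomach surface and mucous glands. The list of these genes was written after the highest genes of this pig had been seen, so it was chosen for the pattern. Of its 11 measured genes 9 lay over 1 log2 unit above the highest of the other 11 pigs. The stomach mucin MUC5AC was at 9.90 in this pig and 5.70 ± 0.232 (SD, n = 11) in the others, an 18.4-fold difference. The gastrokines GKN3 and GKN1 were at 10.51 and 9.67 against 4.76 ± 0.854 and 5.28 ± 1.33, and TFF2, a peptide of mucous glands, was at 13.41 against 9.42 ± 0.791. None of the 7 measured genes of a parietal and chief cell list, which include no pepsinogen, did so: the proton pump subunits ATP4A and ATP4B were at 4.29 and 4.98 in this pig and 3.86 and 4.76 in the others. PGC, the pepsinogen C gene and 1 of the 9 above, was at 5.41 against 3.26. A set of absorptive genes was low in the same pig, with SI at 6.79 against a mean of 9.96 in the other 11 pigs and SLC15A1 at 6.80 against 9.67. These values describe 1 pig and carry no test.

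**Figure D4:**
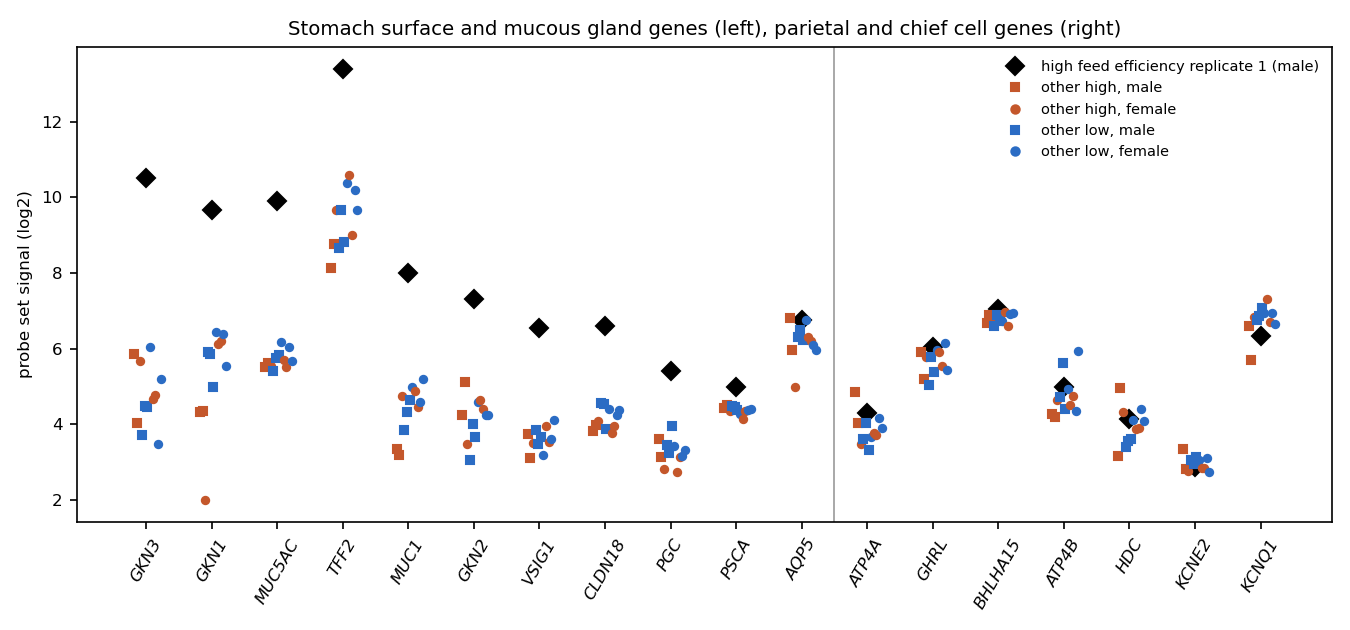
Log2 signal (vertical axis) of 11 stomach surface and mucous gland genes and 7 parietal and chief cell genes in the 12 pigs; the black diamond is high feed efficiency replicate 1, orange and blue symbols are the other high and low feed efficiency pigs, squares males and circles females. The diamond lies over 1 unit above all other pigs for 9 of the 11 genes on the left and for none of the 7 on the right.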

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

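The tests of 1 pig as the source of the list shifts, of compression for the lower lists alone, of stomach mucosa and sampling position in 1 pig and of the Y-chromosome copy of KDM6A, and the fit with array spread as a covariate, were chosen after the result was seen, and the stomach-type gene lists were written after the highest genes of that pig had been seen.

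In each group of 6 pigs, the pig farthest from the others was compared with the whole range of its group for 158 combinations of a list or gene and a group. In 18 of them its gap to the nearest pig, as a share of the range, was above Dixon's critical value for 6 values, where chance gives about 7.9, and 8 of the 18 were high feed efficiency replicate 1. This pig was lowest of its group for enterocyte markers (gap 0.700 of the range, 8.28 against a mean of 9.43 in the other 5), carbohydrate digestion (0.719), protein digestion (0.692), lipid absorption (0.701) and mineral handling (0.808). It was also lowest for SLC15A1 (0.921, 6.80 against 9.74), SI (0.687) and FABP2 (0.723). Low feed efficiency replicate 6 was lowest for enterocyte markers (0.712) and highest for heat shock genes (0.686) and KIF21B (0.669). Low feed efficiency replicate 1 was lowest for macrophage markers (0.637), MHC class II (0.724), insulin and nutrient sensing genes (0.757) and PIGR (0.692). High feed efficiency replicate 6 was lowest for cholesterol synthesis (0.837, 6.70 against 7.25), replicate 4 lowest for endothelial markers (0.676) and replicate 5 highest for mast cell markers (0.686).

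The first pattern was the set of 10 lists lower and 1 higher in high feed efficiency pigs, for which grouping by chance was not excluded, since 31 of 100 splits of the pigs called as many lists (11 in the real split, 22 in the highest other). Signal compression that follows probe set brightness was tested on 10000 random lists matched on mean signal. Of the 11 called lists 6 lay outside the central 95%, which just met the bound of at least 6 written beforehand against compression as the whole cause. That count cannot decide, because the lists were called from these same data. Genes of a list also vary together, at an estimated correlation of 0.26 for the proteasome and 0.41 for ribosomal proteins, which random lists do not copy. Moreover, 6 of 31 uncalled lists lay outside, and 1 of the 6 called ones was the fibroblast list, which is not lower. For the lower lists alone, a narrower count made after that result was seen, 5 of 10 lay outside, which decides neither way. With array spread as a covariate the proteasome and oxidative phosphorylation differences went to -0.04 and -0.01. Lipid absorption and epithelial junctions stayed at -0.30 and -0.13 in that fit (camera adjusted p 0.00683 and 0.0195), and no other lower list passed in its own direction. For the lower lists as a set, compression and a shift of the lists cannot be told apart. Leaving out 1 pig, high feed efficiency replicate 1, left 3 of the 11 lists called (proteasome, oxidative phosphorylation and ribosomal proteins). The mean difference shrank by over 1.5 times in 3 lists only (lipid absorption from -0.27 to -0.09, xenobiotic from -0.22 to -0.07, fibroblast from 0.11 to 0.02), where that pig may carry much of the shift; in the other 8 the size did not shrink so far, a lost call there does not show that the pig carries it, and a difference tied to feed efficiency stays open as untested.

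The second pattern was the stomach-type signal in high feed efficiency replicate 1. Acid-secreting stomach mucosa in the sample stays open: 0 of 7 parietal and chief cell genes lay over 1 log2 unit above the other pigs, but they were listed after top genes that lacked them had been seen, and the pepsinogen gene PGC, held by the other list, lay 1.47 above the highest other pig. A more proximal sampling position stays open: 9 genes of the proximal small intestine had a median deviation of -1.06 from the other 11 pigs, but these include absorptive transporters and leave out TFF2 and PGC, which the stomach list also holds and which were 3.99 and 2.15 above the mean of the others. Pyloric stomach mucosa could be a source: its hormone gene GAST lay 0.268 above the highest other pig (5.46 against a mean of 4.98), between the bounds set, so acid-secreting mucosa, pyloric mucosa and stomach-type cells arising in the jejunum cannot be told apart. The design names no group for 1 pig, so no biological explanation was tested.

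The third pattern was the KDM6A probe set that was higher in males while others of the gene were lower. Signal from the Y-chromosome copy of the gene is a candidate explanation: of the 2 probe sets higher in males, the brighter was at 2.30 in females, 0.4 above the highest negative control mean, which is neither at the floor nor over 1 unit above it, and the dimmer was at 1.82, below that control mean. The array's probes were not placed on a genome, so the X and Y copies cannot be told apart here, and a sex difference in KDM6A expression stays open as untested.

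Grouping by chance was excluded for the 6 probe sets called between males and females, where 1 of 100 splits, the real one, called as many and the highest other called 2. It was not excluded for the 10 lists differing between the sexes, where 43 of 100 splits called as many and the highest other called 22. It was not excluded for the 2789 probe sets at an unadjusted p under 0.05 between high and low feed efficiency, where 13 of 100 splits gave as many and the highest other gave 6908, nor for the 2395 of the interaction, where 15 of 100 gave as many and the highest other gave 6737. Splits with several times the median count of 1415 in the first of these point to a structure of the samples that the groups do not follow. On the main axis of variation among the arrays (26.6% of the variance), high feed efficiency replicates 2, 3 and 4 and low feed efficiency replicate 1 were at 46.1 to 66.6. The other pigs were at -47.4 to 10.8. The ribosomal list was lowest in the same pigs, at 7.81 to 7.98 against 8.23 to 8.53 in the others. Whether this axis lies behind those splits was not tested. Within males and within females the 10 possible splits are too few for a share under 0.05: the real values were 3121 and 1947, the highest others 4953 and 2451, and 2 of 10 splits gave as many in each sex.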

How the results depend on the processing

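The exact permutation of list means and the fit with the spread of each array as a covariate were chosen after seeing the data. No paired analysis was possible because replicate numbers follow the order of the deposited records and pair no pigs. The count of 0 probe sets between high and low feed efficiency held in all alternatives run, and that between the sexes stayed at 4 to 7 except for 0 with the mean of the probe sets of each gene, which drops unnamed probe sets. Gene lists shifted by feed efficiency numbered 4 with array weights, 3 with quantile normalization, 0 with an estimated inter-gene correlation, 0 with fry, 0 with exact permutation, and from 3 to 19 when 1 pig was left out (3 without high feed efficiency replicate 1, 5 without low feed efficiency replicate 1, 19 without low feed efficiency replicate 6). Gene lists shifted by sex numbered 0 with an estimated correlation and 3 with fry. Within males 2 probe sets were called in a fit on the 6 males alone (CYP3A29 and an unnamed one, named after their values were seen), 6 genes with the mean of the probe sets of each gene, and 0 to 3 probe sets when 1 pig was left out (1 without high feed efficiency replicate 1, for a mouse microRNA, and 3 without high feed efficiency replicate 3, 2 of SLC40A1 and 1 of MIR769). Within females 1 was called in a fit on the 6 females alone, and 0 to 1 when 1 pig was left out (1 without low feed efficiency replicate 3), each time GHRH. Among lists called in the main setting or in the alternative, directions turned, male minus female, for endothelial markers (0.15) and ribosomal proteins (0.026) with the identifier run as a block. They also turned for X-linked genes (0.30) with the probe set of the largest variance, where KDM6A enters by its probe set that is higher in males. High minus low, they turned with array spread as a covariate for B cell markers (0.23), ribosomal proteins (0.11), MHC class II (0.18) and antioxidant genes (0.033). The first 3 of these passed in the new direction. That fit called 9 lists, with 3 of the 11 in their own direction and the ribosomal list in the opposite one. Male minus female, ribosomal proteins turned to 0.021 in that fit. The cause was not tested for these changes except where stated. For single named genes 4649 of the values under alternatives kept direction and side of the threshold, 51 turned direction without a call in either setting and 5 gained a call. For lists 1787 kept, 154 turned direction without a call in either setting, 8 turned with a call, 134 lost and 57 gained a call. Signal near the negative controls limits probe sets such as GHRH.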

Other observations

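Several lists not yet described had no shift between high and low feed efficiency by camera. Cell cycle genes had a mean difference of -0.08 (adjusted p 0.366), with the mitotic kinase PLK1 at -0.49 (SE 0.197), and crypt stem cell markers 0.02 (adjusted p 0.450), with the growth factor receptor regulator LRIG1 at 0.49 (SE 0.160). B cell, lymphoid follicle, macrophage and mast cell markers differed by -0.01, -0.06, -0.13 and 0.04 (adjusted p 0.834, 0.898, 0.533 and 0.898), with the mast cell receptor KIT at 0.65 (SE 0.269). MHC class II and epithelial antimicrobial genes differed by -0.10 and -0.09 (adjusted p 0.898 and 0.834). Unfolded protein response, heat shock and immediate early genes differed by -0.09, -0.04 and -0.11 (adjusted p 0.414, 0.701 and 0.450), insulin and nutrient sensing genes by -0.01 (adjusted p 0.851) and mineral handling genes by -0.09 (adjusted p 0.450). Distal small intestine genes, red blood cell genes, enteric neuron and glia markers and X-linked genes with Y copies differed by -0.08, -0.09, 0.04 and 0.03 (adjusted p 0.526, 0.878, 0.878 and 0.701). None of the 42 lists passed for the interaction of feed efficiency and sex by exact permutation (smallest adjusted p 0.420, smallest unadjusted p 0.02, for X-linked genes). That test could pass a list only if several had reached its smallest possible p of 0.005.

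High feed efficiency replicate 1 had 113 probe sets over 1 log2 unit above and 173 over 1 below all other pigs, where the other pigs had at most 50 and 98. Chosen after their values were seen, the genes farthest above included CAPN6 (6.93 against a mean of 2.39 in the other 11 pigs), the chloride exchanger SLC26A3 (8.10 against 3.31) and the somatostatin receptor SSTR2 (6.92 against 3.43). Those farthest below included the amino acid transporter SLC6A19 (5.42 against 8.67), the lipoprotein gene APOC3 (6.23 against 9.71) and the acyltransferase MOGAT1 (4.10 against 7.08). Across 5 equal groups of probe sets ordered by mean signal the median high minus low difference went from 0.04 in the dimmest to -0.08 in the brightest, and the median male minus female difference from 0.06 to -0.10.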
